A study of Danio rerio with 14 samples.

How the data were processed

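Gene expression was measured in whole zebrafish larvae (Danio rerio, AB strain, wild type) by 1-colour microarray. Per the labels, embryos were exposed from 3 h after fertilisation for 5 days to secondary effluent of a wastewater plant in Tucson that had been reconstituted in E3, the standard saline for zebrafish embryos. The effluent was used at its original strength (1x, 5 arrays) or at 0.5x (5 arrays), and 4 control arrays came from larvae kept in the same saline with 0.05% DMSO, the solvent that carried the effluent. Each well held 25 to 30 embryos in 4 mL at 28 °C, its medium was replaced every 24 h, and the larvae of 1 well were pooled as 1 replicate. The p-values of single genes below therefore measure the spread between wells. Those of the list test camera at its preset correlation do not, as explained where camera is introduced. Whether the wells shared a clutch or a collection time is not given in the sources used here. From each replicate, 200 ng of total RNA was amplified and labelled with the dye Cy3, per the labels' protocols.

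The authors deposited the scanner output of each array, made with Agilent Feature Extraction 10.7 per the file headers and the submitters' processing notes. Its processed signal is a linear intensity from which, per the file headers, the software had already subtracted background and removed spatial trends across the glass; no step had yet made arrays comparable with each other. The authors also deposited a matrix of log2 values for 36346 probes, whose making is not given in the sources used here. Compared with the scanner values, the matrix equals the log2 processed signal less each array's 75th percentile, centred for each probe on the median of the arrays of 1 slide. The match gave a correlation of 1.00 on 3 of the 4 slides, and of 0.872 and 0.901 for both arrays of slide 1, whose centring term was not found in the arrays used here. The medians of the matrix columns ran from -0.0662 to 0.110. The matrix was used as an alternative only.

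Each array carried 43803 non-control spots for 43603 probes. Spots marked as outliers by the software (73 over the 14 arrays) were left out, no spot was saturated, and the spots of a probe were averaged. Between 37225 and 39647 probes (85.4% to 90.9%) were well above background on an array, and the median processed signal ran from 132 to 255. The number of arrays limits the precision: the median standard error of a log2 fold change was 0.164 against control and 0.155 between the concentrations.

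The signal was analysed as the log2 intensity less the array's 75th percentile, so all values are relative to that percentile. A probe was kept if well above background on at least 4 arrays of a group, which left 38803 probes. The accession on the array of 25978 probes matched the gene table of the GRCz12tu assembly, which was used for names only, and 24179 probes had a gene symbol. A gene with several probes was represented by the kept probe with the highest mean over all arrays (11907 genes). Where other probes of a named gene moved the other way, the text says so. Groups were compared with limma (version 3.58.1, in R 4.3.3), by lmFit and eBayes on all 14 arrays without a block, with Benjamini-Hochberg adjustment over the probes and a threshold of 0.05. Every adjusted p printed for a gene is limma's. The 3 comparisons were 1x against control, 0.5x against control and 1x against 0.5x.

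Genes were also tested as 40 lists fixed in advance, with limma's camera test on 1 probe per gene. Camera asks whether the genes of a list moved further in a direction than the other genes; it was run with a preset correlation between genes of 0.01 and adjusted over the lists. Beside it stand camera with the correlation estimated from each list and fry, which asks whether the genes of a list move on balance one way and does not compare them with other genes. The lists covered responses to chemicals (AhR targets, estrogen-responsive genes, PXR and phase I metabolism, phase II conjugation, Nrf2 and oxidative stress, metal response, heat shock, ER stress), hormone axes and rhythm (glucocorticoid axis, thyroid axis, circadian clock), metabolism (lipid transport, fatty acid oxidation, fatty acid synthesis, cholesterol synthesis, bile acid metabolism, gluconeogenesis, hypoxia and glycolysis, oxidative phosphorylation), the liver, gut, pancreas and other tissues (hepatocyte, intestinal enterocyte, exocrine pancreas, muscle, phototransduction, lens crystallins, neurons, myelin and glia, ionocytes, skin, extracellular matrix, pigment cells, erythroid cells), immunity (acute phase, neutrophil and macrophage, interferon response) and cell growth (cell cycle, p53 and DNA damage, immediate early genes, ribosomal proteins, proteasome). The number of members past the threshold is given over all probes and, where stated, adjusted over the list alone.

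The groups, tests, lists, rule for named genes and alternatives were chosen before the data were examined, except for 5 alternatives named in the closing section (those by scan day among them) and the tests named there. The rule takes, for each comparison against control, the 10 genes with the largest rise and the 10 with the largest fall among those past the threshold whose arrays did not overlap between the groups (5 and 5 for 1x against 0.5x). To these it adds 27 sentinel genes, of which 24 were measured, and up to 4 members of each list past the threshold with the largest change, or, in a called list with fewer than 2 such members, up to 3 with the smallest p, given as not past the threshold. Where a gene was not well above background on any array of the dimmer group, the change is given as a lower bound, computed against the higher of the probe's own signal and the lowest signal well above background on each array.

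The file headers also place the arrays on 4 slides scanned on 2 days. Slides 1 and 2 (scan day 1) held control replicates 1 and 2, 1x replicates 1 to 3 and 0.5x replicate 1, and slides 3 and 4 (scan day 2) held the others. Slide 1 held no 0.5x array and slide 4 no 1x array. A control lay in array position 1 of every slide, so that position and control cannot be told apart. Comparisons were repeated with slide as a block, within each scan day and with scan day as a block. Other alternatives were normexp background correction with an offset of 50, quantile normalization, median scaling, the authors' matrix, no filter or a stricter filter, only the 2 groups compared, eBayes with trend and robust settings, array weights, the replicate number as a block, a minimum change of 1.5-fold, 1 probe per named gene and leaving out each array in turn. The spot means that normexp was to use were not among the columns of the files used here, so spot medians took their place.

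The test was tested on simulated data made from the spread of the real arrays, with 200 of 38786 probes changed. For 1x against control it recovered 16.4%, 65.7% and 93.9% of changes of 0.5, 1 and 2 on the log2 scale, for 0.5x against control 14.9%, 74.6% and 97.0%, and for 1x against 0.5x 31.3%, 70.2% and 98.5%. The share of false calls was 4.10%, 8.15% and 2.21%. These shares need not hold in the real data, where far more probes were called. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.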

Results

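To investigate how treated wastewater alters gene expression in developing fish, RNA of whole zebrafish larvae was hybridised to 14 1-colour arrays. There were 4 control wells, 5 wells with effluent at 1x and 5 wells with effluent at 0.5x. The median processed signal of an array was 132 to 194 in the control group, 175 to 253 at 1x and 137 to 255 at 0.5x. Over all probes, arrays of the same group correlated at 0.964 to 0.991 (control), 0.987 to 0.995 (1x) and 0.981 to 0.996 (0.5x), and arrays of any pair at 0.953 to 0.996. In a principal component analysis the first component held 38.1% of the variance. The second (25.8%) separated scan day 1 (-49.0 to -26.7) from day 2 (-13.2 to 55.4). On the first, the 1x arrays lay between 13.3 and 44.4 and the 0.5x arrays between -9.07 and 41.7. Control replicates 3 and 4 lay at -17.5 and -8.88, while control replicates 1 and 2, both scanned on day 1, stood apart at -120 and -80.5.

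**Figure D1:**
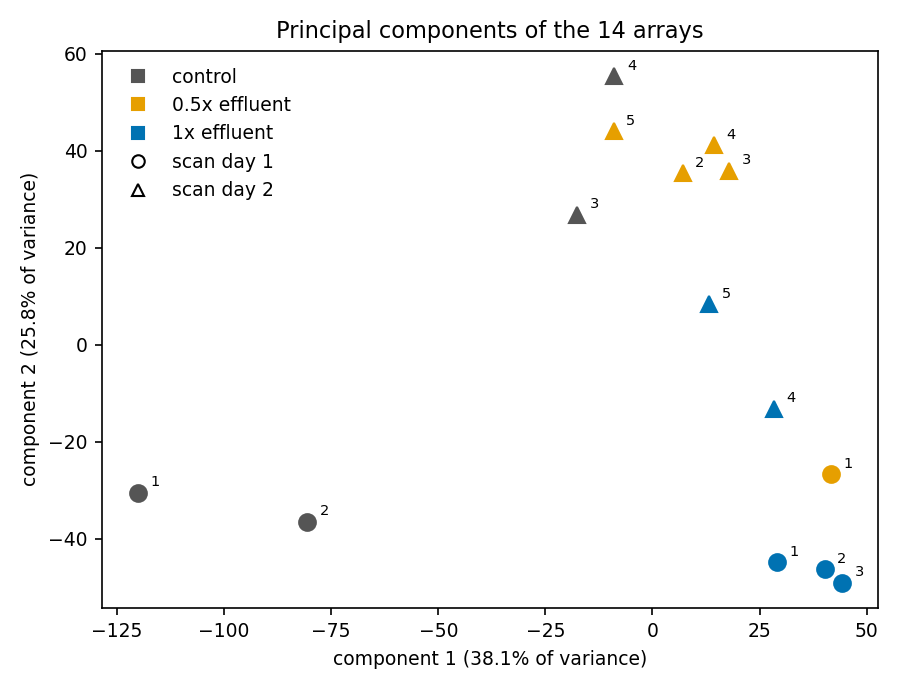
Each point is an array, placed by its scores on the first (38.1% of variance) and second (25.8%) principal components of the log2 signals, coloured by group and shaped by scan day. Control replicates 1 and 2 stand apart on the first component and the scan days on the second.

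The first comparison asked which genes changed in larvae kept in effluent at 1x (n = 5) compared with control larvae (n = 4). At camera's preset correlation, lists of phase I, phase II and cholesterol synthesis rose and those of phototransduction and neurons fell. With an estimated correlation 0 lists passed (4 at an unadjusted p under 0.05), and the medians within scan day 2 were 0.23, 0.25, 0.78, -0.04 and -0.06. Brain aromatase, cyp19a1b, which makes estrogen in radial glia, rose 3.92-fold (log2 fold change 1.97 ± 0.22 SE, adjusted p = 0.00019). The AhR target cyp1a rose 3.44-fold (1.78 ± 0.36, adjusted p = 0.00451), the PXR target cyp3a65 4.01-fold (2.00 ± 0.43, adjusted p = 0.00626) and the sterol demethylase cyp51 by 2.05 ± 0.19 (adjusted p = 6.6e-05). Of 38803 probes, 11167 passed the threshold, 3826 higher and 7341 lower at 1x (34.3% higher). The split moved to 3164 and 13190 (19.4% higher) with normexp, where the median of all probes was -0.20 instead of -0.09, and to 4813 and 6003 (44.5% higher) with quantile normalization. Among 11907 genes, 1214 rose and 1924 fell, of which 216 and 86 by at least 2-fold. The arrays of the groups did not overlap for 20.6% of probes, where chance gives 1.59%. The count was 5963 without control replicate 1 and moved by more than 1.5 times also without control replicate 2 or 1x replicate 3 (its range over arrays left out in turn was 5963 to 13012). With slide as a block it was 14140 (5261 higher, 8879 lower). Within scan day 1 it was 18073 and within scan day 2 it was 1556. Across all probes, which are not independent, the changes within the days correlated at r = 0.422, and 938 probes were called on both days with the same sign.

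The largest fitted rises at 1x included genes not above background in control larvae, whose changes are lower bounds and whose rank cannot be read. The cyclotransferase gene ggact.2 was at least 13.4-fold higher (adjusted p = 0.00141), the green opsin opn1mw4 at least 2.80-fold (adjusted p = 0.000117) and the kinase gene pimr132 at least 2.86-fold (adjusted p = 0.000948). All 3 were well above background in 0 of 4 control and 5 of 5 1x arrays. The bounds of the oocyte factor gdf9 (at least 1.23-fold, adjusted p = 0.000935) and of ggact.3 (at least 1.13-fold, adjusted p = 0.00293, well above background on 4 of 5 arrays) lay close to 1, and gdf9 had a log2 fold change of -0.12 with normexp. The testis determinant dmrt1 rose by 2.63 ± 0.28 on the log2 scale (adjusted p = 0.000128). So did the P450 genes cyp2k19 (2.43 ± 0.22, adjusted p = 4.51e-05) and cyp2x10.2 (2.36 ± 0.36, adjusted p = 0.00117) and the glucuronosyltransferase ugt5a4 (2.24 ± 0.25, adjusted p = 0.000188). The glutathione transferase gstp1.1 rose by 2.83 ± 0.83 (adjusted p = 0.0226), by 5.14 within scan day 1 and by 0.48 within scan day 2. Its adjusted p was 0.0697 to 0.0733 without control replicate 1 or 2 (0.00191 to 0.36 over all alternatives). Of the 5 probes of cyp2k19, 4 moved up.

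The largest falls were in jac10 (-2.57 ± 0.20, adjusted p = 1.84e-05), tmem45a (-1.98 ± 0.28, adjusted p = 0.000779), prrg1 (-1.88 ± 0.26, adjusted p = 0.000738) and the cilia gene ccdc40 (-1.75 ± 0.16, adjusted p = 4.51e-05). The other probe of tmem45a did not move down. Then came tapbp.2, a tapasin that loads antigens (-1.74 ± 0.30, adjusted p = 0.00211), and rela, a subunit of NF-kappaB (-1.66 ± 0.18, adjusted p = 0.000128). The others were zbtb12.1 (-1.74 ± 0.23, adjusted p = 0.000518), the granulin gene grna.1 (-1.63 ± 0.21, adjusted p = 0.000422), klhl5 (-1.60 ± 0.19, adjusted p = 0.000276) and ft1 (-1.69 ± 0.45, adjusted p = 0.0149). Without control replicate 1, ft1 had an adjusted p of 0.0544 (0.00409 to 0.176 over all alternatives).

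Targets of the dioxin receptor AhR rose as a list (11 genes, median log2 0.59, adjusted p = 0.000311; adjusted p = 0.125 with an estimated correlation). Of its genes 6 rose, and 7 adjusted over the list alone. The medians within scan days 1 and 2 were 0.87 and 0.32. Besides cyp1a (2.53 and 1.13 within the days), cyp1b1 (0.71 ± 0.14, adjusted p = 0.00407), cyp1c1 (1.28 ± 0.20, adjusted p = 0.00129), cyp1c2 (0.59 ± 0.14, adjusted p = 0.0096) and the receptor's repressor ahrra (1.39 ± 0.21, adjusted p = 0.00101) rose. Its paralog ahrrb stood at 0.12 (adjusted p = 0.634), and the other probe of cyp1c2 did not move up. PXR and phase I metabolism rose (34 genes, median 0.58, adjusted p = 1.41e-07; adjusted p = 0.319 with an estimated correlation), with 19 genes up and 1 down over all probes and 21 and 1 adjusted over the list alone. Phase II conjugation rose likewise (38 genes, 20 up and 1 down, 22 and 2 adjusted over the list alone, median 0.65, adjusted p = 3.21e-07; adjusted p = 0.319 with an estimated correlation). The glucuronosyltransferase ugt1a7 rose by 1.63 ± 0.35 (adjusted p = 0.00641). Nrf2 and oxidative stress genes rose (25 genes, 9 up and 3 down, 12 and 3 adjusted over the list alone, median 0.38, adjusted p = 0.000551; adjusted p = 0.486 with an estimated correlation), among them nqo1 (0.96 ± 0.19, adjusted p = 0.00408). These 3 lists were low in control replicates 1 and 2. Their medians within scan days 1 and 2 were 1.04 and 0.23 (phase I), 1.19 and 0.25 (phase II) and 0.64 and 0.03 (Nrf2), and cyp3a65 rose by 3.08 and 0.95. The heme oxygenase hmox1a had 0.95 ± 0.34 (adjusted p = 0.0466), 1.87 within day 1 and -0.12 within day 2. Its call was lost without control replicate 1 or 2, 1x replicate 1, 2, 3 or 4 or 0.5x replicate 2, 3, 4 or 5 (adjusted p 0.0507 to 0.159; 0.00534 to 0.827 over all alternatives). The glutathione synthesis gene gclc (0.18, adjusted p = 0.192; 1 of 3 probes up) and hsp70l (0.28, adjusted p = 0.158) did not pass. Metallothionein mt2 fell (-1.15 ± 0.14, adjusted p = 0.000311).

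Among estrogen-responsive genes, cyp19a1b and the yolk protein gene vtg7 (1.98 ± 0.35, adjusted p = 0.0024) rose, 2 of 7 measured genes, and the list did not pass (median 0.02, adjusted p = 0.153). Values of vtg2 (0.02, adjusted p = 0.944), vtg5 (-0.02, adjusted p = 0.951) and the receptor esr1 (-0.33, adjusted p = 0.139) did not pass. With normexp vtg2 was lower, at -0.35 and past the threshold.

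Genes of cholesterol synthesis rose (26 genes, median 0.63, adjusted p = 2.06e-12; adjusted p = 0.125 with an estimated correlation), 16 over all probes and 17 adjusted over the list alone. The medians within scan days 1 and 2 were 0.70 and 0.78. Besides cyp51, the squalene epoxidase sqlea rose by 1.99 ± 0.22 (adjusted p = 0.000191), lss by 1.74 ± 0.19 (adjusted p = 0.000147) and msmo1 by 1.65 ± 0.19 (adjusted p = 0.000193). Fatty acid oxidation genes rose (37 genes, 15 up and 3 down, 17 and 3 adjusted over the list alone, median 0.26, 0.46 and 0.19 within the days, adjusted p = 3.55e-05; adjusted p = 0.319 with an estimated correlation), with the thiolase acaa1 at 1.17 ± 0.15 (adjusted p = 0.000422). Bile acid metabolism rose (13 genes, 6 up and 1 down, 10 and 1 adjusted over the list alone, median 0.64, 0.81 and 0.17 within the days, adjusted p = 0.00144; adjusted p = 0.337 with an estimated correlation). Its rate-limiting enzyme cyp7a1 rose by 1.68 ± 0.43 (adjusted p = 0.0133), by 2.99 and 0.22 within the days, with 2 of 3 probes up. The repressor nr0b2a fell (-1.04 ± 0.20, adjusted p = 0.00344). The gluconeogenic enzyme pck1 rose by 1.69 ± 0.28 (adjusted p = 0.00163).

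Hepatocyte genes rose (43 genes, 17 over all probes, 22 up and 1 down adjusted over the list alone, median 0.78, adjusted p = 3.72e-08; adjusted p = 0.486 with an estimated correlation and 0.0981 with fry). Examples were the steroid carrier shbg (1.77 ± 0.33, adjusted p = 0.00308) and complement factor cfh (1.81 ± 0.49, adjusted p = 0.0163). The list's median was 1.72 within scan day 1 and -0.01 within scan day 2, and shbg rose by 2.73 and 0.73. Enterocyte genes rose (37 genes, 7 over all probes and 5 adjusted over the list alone, median 0.47, adjusted p = 0.000139; adjusted p = 0.599 with an estimated correlation), with medians of 1.13 and -0.18 within the days. Lipid transport rose (36 genes, 9 up and 2 down, the same numbers adjusted over the list alone, median 0.25, 0.82 and -0.04 within the days, adjusted p = 0.0273; adjusted p = 0.694 with an estimated correlation). The apolipoprotein apoa4b.2 rose by 1.37 ± 0.35 (adjusted p = 0.0135), by 2.45 and 0.19 within the days. Acute phase genes rose (43 genes, 7 up and 2 down, the same adjusted over the list alone, median 0.30, 0.58 and -0.11 within the days, adjusted p = 0.00541; adjusted p = 0.486 with an estimated correlation), with the cytokine signalling inhibitor socs3a at 1.07 ± 0.20 (adjusted p = 0.00331). Lipid transport lost its call without control replicate 1 or 2 (adjusted p 0.135 to 0.314; 1.02e-05 to 0.694 over all alternatives), and acute phase without control replicate 1 or 1x replicate 3 (0.0731 to 0.0823; 0.000546 to 0.647). Control replicates 1 to 4 deviated from the mean of all arrays by -1.73, -1.07, 0.07 and 0.38 in hepatocyte genes, by -2.49, -1.75, 0.72 and 1.12 in exocrine pancreas genes and by -1.1, -0.94, 0.18 and 0.19 in enterocyte genes. Exocrine pancreas did not pass (24 genes, median 0.45, 2.03 and -1.28 within the days, adjusted p = 0.0601). Limma called 0 of its genes, with 1 at an unadjusted p under 0.05. Leaving out control replicate 3 or 4 or 1x replicate 1, 4 or 5 brought the list past the threshold (adjusted p 0.000103 to 0.0456), as did slide as a block (0.59, adjusted p = 0.0324; 1.43e-17 to 0.856 over all alternatives).

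Phototransduction genes fell (49 genes, 2 up and 20 down, 3 and 21 adjusted over the list alone, median -0.32, adjusted p = 5.85e-05; adjusted p = 0.486 with an estimated correlation). The rod and cone genes guca1aa (-1.52 ± 0.18, adjusted p = 0.000311) and pde6ga (-1.29 ± 0.16, adjusted p = 0.000418) fell, whereas opn1mw4 rose. Neuron genes fell (69 genes, 2 up and 25 down, 4 and 32 adjusted over the list alone, median -0.36, adjusted p = 8.43e-05; adjusted p = 0.486 with an estimated correlation), among them acetylcholinesterase ache (-1.09 ± 0.20, adjusted p = 0.00304) and stxbp1b (-1.16 ± 0.23, adjusted p = 0.00398). The medians within scan days 1 and 2 were -0.60 and -0.04 for phototransduction and -0.61 and -0.06 for neurons. Ribosomal proteins fell (88 genes, 1 up and 10 down, median -0.24, -0.21 and -0.24 within the days, adjusted p = 8.43e-05; adjusted p = 0.694 with an estimated correlation). Limma called 0 of them adjusted over the list alone, with 2 up and 36 down at an unadjusted p under 0.05. With quantile normalization their median was 0.01. Of these rps6ka3b (-0.53 ± 0.13, adjusted p = 0.00998) is a kinase.

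Cell cycle genes rose (60 genes, 22 over all probes and 29 adjusted over the list alone, median 0.30, 0.12 and 0.50 within the days, adjusted p = 3.91e-09; adjusted p = 0.337 with an estimated correlation), among them rpa2 (0.79 ± 0.12, adjusted p = 0.000916) and mad2l1 (0.64 ± 0.10, adjusted p = 0.00146). Proteasome subunits rose (45 genes, 10 by both adjustments, adjusted over the list alone included, median 0.18, 0.19 and 0.26 within the days, adjusted p = 5.7e-06; adjusted p = 0.319 with an estimated correlation), with psmd12 at 0.63 ± 0.09 (adjusted p = 0.00107). Immediate early genes rose (39 genes, 16 up and 4 down, 18 and 4 adjusted over the list alone, median 0.22, 0.25 and 0.21 within the days, adjusted p = 2.91e-05; adjusted p = 0.319 with an estimated correlation). Among them fosab rose by 1.35 ± 0.20 (adjusted p = 0.000935) and npas4a by 1.21 ± 0.12 (adjusted p = 6.94e-05; 1 of 3 probes up). ER stress genes rose (25 genes, 5 up and 1 down by both adjustments, adjusted over the list alone included, median 0.34, 0.22 and 0.25 within the days, adjusted p = 0.00192; adjusted p = 0.392 with an estimated correlation), with manf at 0.75 ± 0.13 (adjusted p = 0.0024). Genes of p53 and DNA damage rose (29 genes, 9 up and 3 down by both adjustments, adjusted over the list alone included, median 0.11, 0.09 and 0.19 within the days, adjusted p = 0.021; adjusted p = 0.319 with an estimated correlation), with gadd45ab at 0.96 ± 0.15 (adjusted p = 0.00123). Erythroid genes rose (32 genes, 13 up and 4 down, 17 and 5 adjusted over the list alone, median 0.46, 0.52 and 0.17 within the days, adjusted p = 0.00435; adjusted p = 0.319 with an estimated correlation). The heme synthesis gene alas1 rose by 1.2 ± 0.21 (adjusted p = 0.00244), while the mitochondrial iron importer slc25a37 fell by 1.57 (SE 0.13, adjusted p = 3.58e-05; 3 of 5 probes down).

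Hormone axes did not pass as lists at 1x. The glucocorticoid axis had a median of -0.10 (20 genes, 6 up and 5 down, adjusted p = 0.561, with the test's direction up), the circadian clock -0.07 (36 genes, 5 up and 9 down, adjusted p = 0.626) and the thyroid axis -0.01 (13 genes, 2 up and 3 down, adjusted p = 0.81, direction up). Single members passed: the glucocorticoid targets klf9 (1.01 ± 0.14, adjusted p = 0.000778) and fkbp5 (1.22 ± 0.29, adjusted p = 0.0103) rose, and the clock genes per1a (-0.91 ± 0.23, adjusted p = 0.0121), dbpa (-1.21 ± 0.18, adjusted p = 0.000935) and aanat2, which makes melatonin (-1.05 ± 0.17, adjusted p = 0.00163), fell. The deiodinase dio1 (0.66 ± 0.19, adjusted p = 0.022) and the receptor thrb (-0.45 ± 0.14, adjusted p = 0.0301) passed. The call of dio1 was lost without control replicate 1 or 2 (adjusted p 0.0729 to 0.0782; 0.00344 to 0.566 over all alternatives), and that of thrb without control replicate 1 or 2 or 1x replicate 1, 2 or 3 (0.051 to 0.0934; 0.00838 to 0.769). Values of dio2 (-0.47, adjusted p = 0.142) and tshba (0.54, adjusted p = 0.302) did not pass, except without control replicate 3 for dio2 and control replicate 4 for tshba (adjusted p 0.0447 and 0.0357). The liver fatty acid binding protein fabp10a stood at 0.14 (adjusted p = 0.672). In all, 15 of the 24 measured sentinel genes passed.

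The other lists did not pass at 1x. Their medians and adjusted p were 0.38 (0.1) for gluconeogenesis, 0.15 (0.145) for hypoxia and glycolysis, 0.02 (0.148) for oxidative phosphorylation, 0.12 (0.153) for heat shock and 0.04 (0.272) for ionocytes. They were -0.23 (0.374) for the interferon response, 0.08 (0.436) for the metal response, 0.02 (0.447) for skin, -0.08 (0.447) for myelin and glia and 0.04 (0.476) for extracellular matrix. They were 0.17 (0.51) for lens crystallins (0 genes up and 10 down in limma over all probes), -0.17 (0.52) for pigment cells, -0.08 (0.595) for muscle, -0.09 (0.603) for fatty acid synthesis and 0.09 (0.626) for neutrophils and macrophages. Of these, gluconeogenesis passed without control replicate 3 or 4, oxidative phosphorylation without control replicate 3 or 4 or 1x replicate 2, and lens crystallins and skin without control replicate 4. The authors' matrix brought gluconeogenesis (0.36, 0.035) and the interferon response (-0.31, 0.0274) past the threshold. Oxidative phosphorylation also passed with slide as a block (0.10, adjusted p = 0.000776; 0.000481 to 0.927 over all alternatives). In the interferon list the RNA sensor dhx58 (-1.46 ± 0.31, adjusted p = 0.00562) and b2m (-1.32 ± 0.28, adjusted p = 0.00543) fell. In all, 20 lists passed, 17 up and 3 down, 0 by camera with an estimated correlation (4 at an unadjusted p under 0.05) and 19 with fry.

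**Figure D2:**
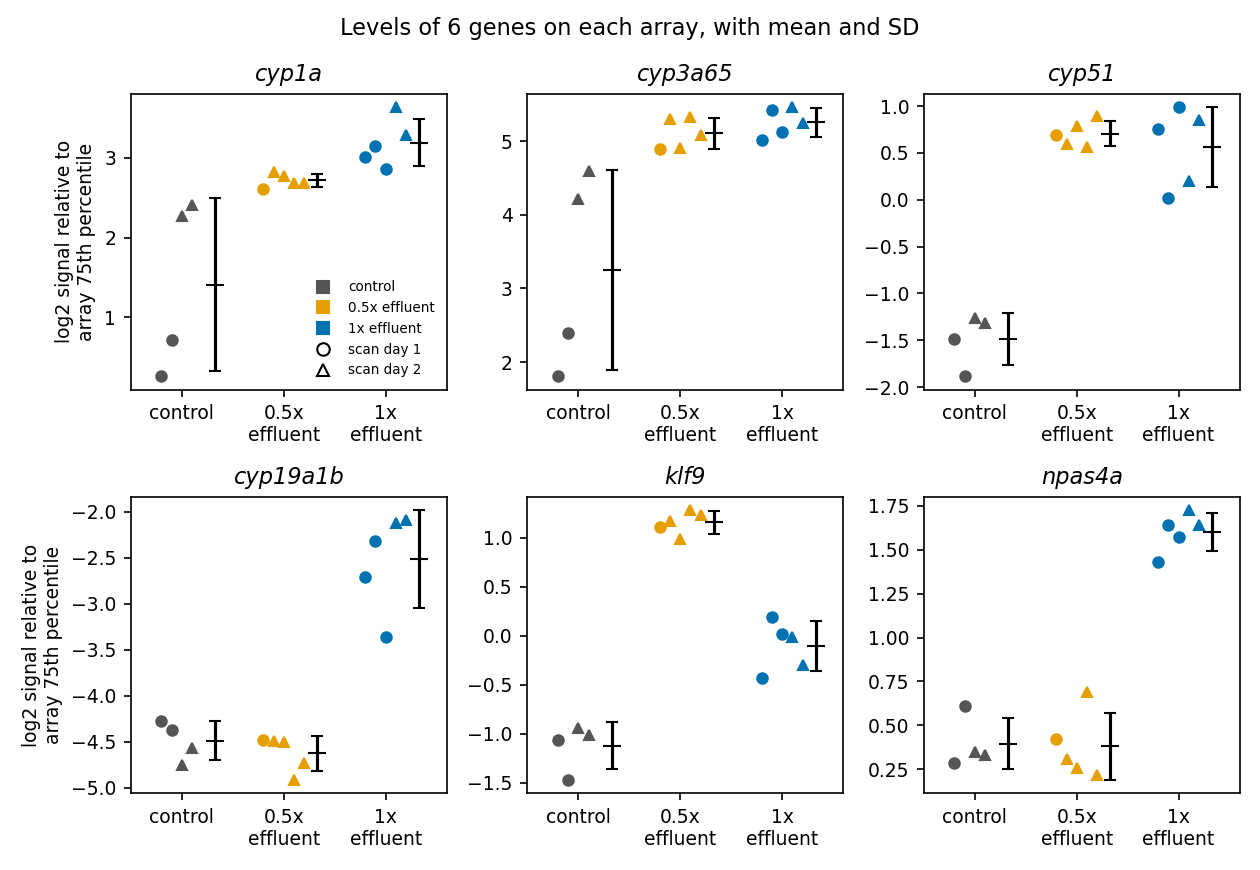
Log2 signal relative to each array's 75th percentile for 6 genes in the control (n = 4), 1x (n = 5) and 0.5x (n = 5) groups, with a point per array (circle for scan day 1, triangle for scan day 2) and bars for mean ± SD. The cyp19a1b arrays at 1x lie above the others (log2 fold change 1.97 against control), whereas klf9 is highest at 0.5x (2.27 against control).

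The second comparison asked which genes changed at 0.5x (n = 5) compared with the same control larvae. At camera's preset correlation, lists of the glucocorticoid axis, the circadian clock, cholesterol synthesis, hepatocytes and enterocytes rose. With an estimated correlation 0 lists passed (8 at an unadjusted p under 0.05), and the hepatocyte and enterocyte medians within scan day 2 were -0.01 and 0.09. The hormone-induced transcription factor klf9 rose 4.84-fold (log2 2.27 ± 0.14, adjusted p = 2.62e-06), the receptor co-chaperone fkbp5 4.02-fold (2.01 ± 0.29, adjusted p = 0.00153) and the mitochondrial carrier ucp3 3.74-fold (1.90 ± 0.13, adjusted p = 4.03e-06). Brain aromatase cyp19a1b stood at -0.13 (adjusted p = 0.697). Of 38803 probes, 3604 passed, 1367 higher and 2237 lower (37.9% higher). The split moved to 1606 and 1339 (54.5% higher) with quantile normalization and to 1505 and 1265 (54.3%) with median scaling. The median of all probes was -0.11. Among genes, 513 rose and 489 fell, 158 and 31 of them by at least 2-fold. Arrays did not overlap for 4169 of the 38803 probes, where chance gives 1.59% of all probes. The count ran from 1114 without control replicate 2 to 9667 without control replicate 4, and moved by more than 1.5 times also without control replicate 1 or 3 or 0.5x replicate 1, 2, 3 or 4. With slide as a block it was 2738 (1089 higher, 1649 lower). Within scan day 2 it was 834 (day 1 held 1 array at 0.5x). The changes within the days correlated at r = 0.301 across all probes.

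Besides klf9, fkbp5 and ucp3, the largest rises were in opn1mw4 (at least 1.82-fold, adjusted p = 0.000473), cyp51 (2.2 ± 0.19, adjusted p = 5.24e-05; 3 of 4 probes up), the glucose phosphatase g6pc1a.2 (2.06 ± 0.32, adjusted p = 0.00225) and the amidase ntan1 (2.03 ± 0.25, adjusted p = 0.000549). The P450 genes cyp2x9 (1.95 ± 0.38, adjusted p = 0.00917), cyp2x8 (1.89 ± 0.42, adjusted p = 0.016) and cyp3a65 (1.85 ± 0.43, adjusted p = 0.0207) rose too, by 3.04, 3.34 and 2.79 within scan day 1 and by 0.91, 0.69 and 0.76 within scan day 2. With slide as a block cyp2x8 stood at 1.52 (adjusted p = 0.0504), and without control replicate 2 its adjusted p was 0.0634 (0.00106 to 0.0679 over all alternatives). That of cyp3a65 was 0.0549 to 0.0779 without control replicate 1 or 2 (0.00127 to 0.0779).

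The largest falls included the collagen chaperone serpinh1b (-1.54 ± 0.15, adjusted p = 9.52e-05), jac10 (-1.68 ± 0.20, adjusted p = 0.000407), the hair cell factor atoh1b (-1.59 ± 0.21, adjusted p = 0.000811) and illr1 (-1.30 ± 0.20, adjusted p = 0.00212). Also lower were dhx58 (-1.68 ± 0.31, adjusted p = 0.00615), acod1 (-1.49 ± 0.26, adjusted p = 0.00491), the chemokine ccl34a.4 (-1.57 ± 0.42, adjusted p = 0.0348) and the interferon factor irf1b (-1.49 ± 0.36, adjusted p = 0.0238). The transferrin receptor tfr2 (-1.48 ± 0.36, adjusted p = 0.0249) and jac11 (-1.47 ± 0.36, adjusted p = 0.0238) fell. Of these calls, 4 lay close to the threshold. That of ccl34a.4 was lost without control replicate 2 or 3 or 0.5x replicate 1, 3, 4 or 5 (adjusted p 0.051 to 0.0874; 0.019 to 0.288 over all alternatives), and that of irf1b without control replicate 2 or 0.5x replicate 3 (0.0559 to 0.0602; 0.00573 to 0.55). That of tfr2 was lost without control replicate 1 or 2 or 0.5x replicate 1 or 4 (0.0522 to 0.0804; 0.000877 to 0.177), and that of jac11 without control replicate 1 or 0.5x replicate 3 (0.0529 to 0.059; 0.00396 to 0.454).

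The glucocorticoid axis rose (20 genes, 7 up and 1 down, 10 and 3 adjusted over the list alone, median 0.28, 0.40 and 0.13 within the days, adjusted p = 0.000634; adjusted p = 0.0846 with an estimated correlation). Besides klf9 and fkbp5, tsc22d3 rose by 1.21 ± 0.13 (adjusted p = 0.000222). The circadian clock rose (36 genes, 12 up and 2 down, 13 and 4 adjusted over the list alone, median 0.19, 0.13 and 0.27 within the days, adjusted p = 0.000118; adjusted p = 0.25 with an estimated correlation). The period gene per1b rose by 1.55 ± 0.14 (adjusted p = 5.24e-05), the repressors nfil3-6 by 1.27 ± 0.15 (adjusted p = 0.000365) and nr1d1 by 1.26 ± 0.15 (adjusted p = 0.00037), while per1a stood at -0.13 (adjusted p = 0.705; 1 of 2 probes down). Hypoxia and glycolysis genes rose (31 genes, 4 up and 1 down, 5 and 3 adjusted over the list alone, median 0.12, 0.16 and 0.12 within the days, adjusted p = 0.0173; adjusted p = 0.126 with an estimated correlation). Its members pfkfb4b (1.62 ± 0.09, adjusted p = 1.77e-06) and ddit4 (1.84 ± 0.19, adjusted p = 0.000154) rose. The list's call was lost without control replicate 4 (adjusted p = 0.091; 0.00123 to 0.131 over all alternatives). Immediate early genes rose (39 genes, 10 up and 2 down, 12 and 4 adjusted over the list alone, median 0.08, 0.07 and 0.15 within the days, adjusted p = 0.00216; adjusted p = 0.385 with an estimated correlation), among them nr4a1 (1.16 ± 0.13, adjusted p = 0.000216). Genes of p53 and DNA damage rose (29 genes, 3 over all probes and 4 adjusted over the list alone, median 0.12, 0.12 and 0.10 within the days, adjusted p = 0.00771; adjusted p = 0.202 with an estimated correlation), with gadd45ab at 1.21 ± 0.15 (adjusted p = 0.000464).

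Cholesterol synthesis rose (26 genes, 13 over all probes and 18 adjusted over the list alone, median 0.64, 0.39 and 0.70 within the days, adjusted p = 1e-12; adjusted p = 0.0994 with an estimated correlation). Besides cyp51, msmo1 rose by 1.53 ± 0.19 (adjusted p = 0.000446), sqlea by 1.38 ± 0.22 (adjusted p = 0.00305) and lss by 1.32 ± 0.19 (adjusted p = 0.00131). Fatty acid oxidation genes rose (37 genes, 9 over all probes, 15 up and 1 down adjusted over the list alone, median 0.29, 0.41 and 0.10 within the days, adjusted p = 9.08e-08; adjusted p = 0.202 with an estimated correlation), with the oxidase acox3 at 1.76 ± 0.22 (adjusted p = 0.000564). AhR targets rose (11 genes, 4 over all probes and 7 adjusted over the list alone, median 0.46, 0.59 and 0.35 within the days, adjusted p = 0.000592; adjusted p = 0.11 with an estimated correlation). Of these, cyp1c1 (1.01 ± 0.20, adjusted p = 0.0103; 2 of 3 probes up) and ahrra (1.05 ± 0.21, adjusted p = 0.00949) rose. The change of cyp1a was 1.31 ± 0.36 (adjusted p = 0.0368), 2.12 and 0.41 within the days and 0.97 with slide as a block (adjusted p = 0.0614). Its call was lost without control replicate 1 or 2 or any 1 of the 0.5x replicates 1 to 5 (adjusted p 0.051 to 0.124; 0.00312 to 0.328 over all alternatives). Values of cyp1b1 (0.45, adjusted p = 0.0545), cyp1c2 (0.46, adjusted p = 0.0553) and ahrrb (-0.15, adjusted p = 0.573) did not pass. The first passed without control replicate 4, 1x replicate 3 or 0.5x replicate 1, and cyp1c2 without control replicate 3 or 4.

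The lists of the liver, gut and pancreas rose, and did so within scan day 1. Hepatocyte genes rose (43 genes, 6 over all probes and 16 adjusted over the list alone, adjusted p = 2.02e-10; adjusted p = 0.406 with an estimated correlation), with a median of 0.78, 1.60 within day 1 and -0.01 within day 2. The tryptophan dioxygenase tdo2b rose by 1.1 ± 0.22 (adjusted p = 0.0104). Enterocyte genes rose (37 genes, 9 over all probes and 19 adjusted over the list alone, adjusted p = 2.02e-10; adjusted p = 0.345 with an estimated correlation), with a median of 0.69, 1.33 and 0.09 within the days. Exocrine pancreas rose (24 genes, median 1.12, 2.67 and -0.39 within the days, adjusted p = 7.18e-05; adjusted p = 0.559 with an estimated correlation). Limma called 0 of its genes, also adjusted over the list alone, with 4 at an unadjusted p under 0.05. The digestive enzymes cel.2 (1.46 ± 0.51, adjusted p = 0.077), cpa4 (1.62 ± 0.60, adjusted p = 0.0928) and ela3l (1.4 ± 0.56, adjusted p = 0.112) did not pass, except without control replicate 3 or 4. Lipid transport rose (36 genes, 5 over all probes, 14 up and 2 down adjusted over the list alone, median 0.54, 0.69 and 0.12 within the days, adjusted p = 4.19e-05; adjusted p = 0.385 with an estimated correlation). Gluconeogenesis rose (25 genes, 4 over all probes, 11 up and 1 down adjusted over the list alone, median 0.60, 1.19 and 0.08 within the days, adjusted p = 7.18e-05; adjusted p = 0.317 with an estimated correlation), with pck1 at 1.66 ± 0.28 (adjusted p = 0.00354). Bile acid metabolism rose (13 genes, 2 over all probes and 8 adjusted over the list alone, median 0.45, 0.62 and 0.13 within the days, adjusted p = 0.000625; adjusted p = 0.279 with an estimated correlation). The change of cyp7a1 was 1.84 ± 0.43 (adjusted p = 0.0208; 2 of 3 probes up), 3.43 and 0.68 within the days and 1.51 with slide as a block (adjusted p = 0.0629). Its adjusted p was 0.0595 to 0.0774 without control replicate 1 or 2 (0.00287 to 0.211 over all alternatives). PXR and phase I metabolism rose (34 genes, 12 over all probes and 19 adjusted over the list alone, median 0.49, 0.90 and 0.14 within the days, adjusted p = 2.61e-08; adjusted p = 0.239 with an estimated correlation). Phase II conjugation rose (38 genes, 12 up and 1 down, 23 and 3 adjusted over the list alone, median 0.74, 1.27 and 0.13 within the days, adjusted p = 4.19e-07; adjusted p = 0.279 with an estimated correlation), with ugt5a1 at 1.35 ± 0.19 (adjusted p = 0.00133). Nrf2 and oxidative stress genes rose (25 genes, 4 up and 1 down, 13 and 3 adjusted over the list alone, median 0.39, 0.66 and 0.11 within the days, adjusted p = 4.19e-05; adjusted p = 0.371 with an estimated correlation), with nqo1 at 1.02 ± 0.19 (adjusted p = 0.0064). The change of hmox1a was 1.12 ± 0.34 (adjusted p = 0.0495) and 0.85 with slide as a block (adjusted p = 0.128). Its call was lost without control replicate 1 or 2, any 1 of the 1x replicates 1 to 5 or 0.5x replicate 1, 2, 3 or 4 (adjusted p 0.0516 to 0.16; 0.00797 to 0.497 over all alternatives).

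Other lists passed at 0.5x too. Erythroid genes rose (32 genes, 6 up and 1 down, 6 and 2 adjusted over the list alone, median 0.14, 0.32 and 0.08 within the days, adjusted p = 0.0198; adjusted p = 0.25 with an estimated correlation), among them alas1 (1.06 ± 0.21, adjusted p = 0.00986). Without control replicate 1 the list had an adjusted p of 0.0553 (0.00328 to 0.25 over all alternatives). Skin rose (32 genes, 3 over all probes and 4 adjusted over the list alone, median 0.19, 0.32 and 0.01 within the days, adjusted p = 0.000737; adjusted p = 0.504 with an estimated correlation). Lens crystallins rose (57 genes, 1 over all probes, 25 up and 1 down at an unadjusted p under 0.05 and 0 by limma adjusted over the list alone, median 0.49, 0.77 and -0.04 within the days, adjusted p = 0.000125; adjusted p = 0.559 with an estimated correlation). Oxidative phosphorylation rose (89 genes, 1 up and 1 down, median 0.16, 0.04 and 0.03 within the days, adjusted p = 0.000109; adjusted p = 0.658 with an estimated correlation), although its member ndufa12 fell (-0.63 ± 0.12, adjusted p = 0.0065). The list did not pass with slide as a block (0.03, adjusted p = 0.131; 8.84e-10 to 0.658 over all alternatives). Proteasome subunits rose (45 genes, median 0.09, 0.06 within each day, adjusted p = 0.00436; adjusted p = 0.433 with an estimated correlation). Limma called 0 of them, also adjusted over the list alone, with 5 at an unadjusted p under 0.05; psmb7 stood at 0.30 (adjusted p = 0.0518) and psmd12 at 0.27 (adjusted p = 0.0754). Cell cycle genes rose (60 genes, 3 over all probes and 1 adjusted over the list alone, median 0.07, -0.07 and 0.25 within the days, adjusted p = 0.0279; adjusted p = 0.706 with an estimated correlation). That call was lost without control replicate 3 or 4 or 0.5x replicate 1 or 3 (adjusted p 0.0559 to 0.49; 6.31e-09 to 0.93 over all alternatives). Neuron genes fell (69 genes, 4 up and 2 down, 4 and 6 adjusted over the list alone, median -0.21, -0.61 and 0.04 within the days, adjusted p = 0.0256; adjusted p = 0.68 with an estimated correlation). That call was lost without control replicate 1 or 2 or 0.5x replicate 1 (adjusted p 0.0895 to 0.107; 1.92e-05 to 0.868 over all alternatives) and with slide as a block (-0.17, adjusted p = 0.14).

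In all, 24 lists passed at 0.5x, 23 up and 1 down, 0 by camera with an estimated correlation (8 at an unadjusted p under 0.05) and 17 with fry. The other 16 had an adjusted p between 0.0658 (phototransduction, median -0.21, -0.62 and 0.05 within the days) and 0.838 (heat shock, median -0.02). Phototransduction passed without control replicate 3 or 4 or 0.5x replicate 2 or 4, ER stress (0.06, adjusted p = 0.108) without control replicate 2, the interferon response (-0.25, adjusted p = 0.184) without 0.5x replicate 1 and ribosomal proteins (0.00, adjusted p = 0.383) without control replicate 4 or 0.5x replicate 1. Ionocytes (0.08, adjusted p = 0.0754) passed with slide as a block (0.03, adjusted p = 0.0498; highest 0.266 over all alternatives). Of the 24 measured sentinel genes 9 passed. Among these, esr1 stood at -0.57 ± 0.16 (adjusted p = 0.0455) and at -0.53 with slide as a block (adjusted p = 0.0634). Its call was lost without control replicate 1 or 2, 1x replicate 1 or 3 or 0.5x replicate 1, 2, 3 or 4 (adjusted p 0.0512 to 0.145; 0.0132 to 0.416 over all alternatives). Values of vtg2 (-0.05, adjusted p = 0.862), vtg5 (-0.15, adjusted p = 0.688), mt2 (-0.19, adjusted p = 0.367), hsp70l (-0.10, adjusted p = 0.672), gclc (0.09, adjusted p = 0.569) and dio2 (-0.36, adjusted p = 0.305) did not pass. Those of dio1 (0.43, adjusted p = 0.142), thrb (-0.36, adjusted p = 0.107), tshba (1.18, adjusted p = 0.0665) and fabp10a (0.47, adjusted p = 0.183) did not pass, except without control replicate 4.

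**Figure D3:**
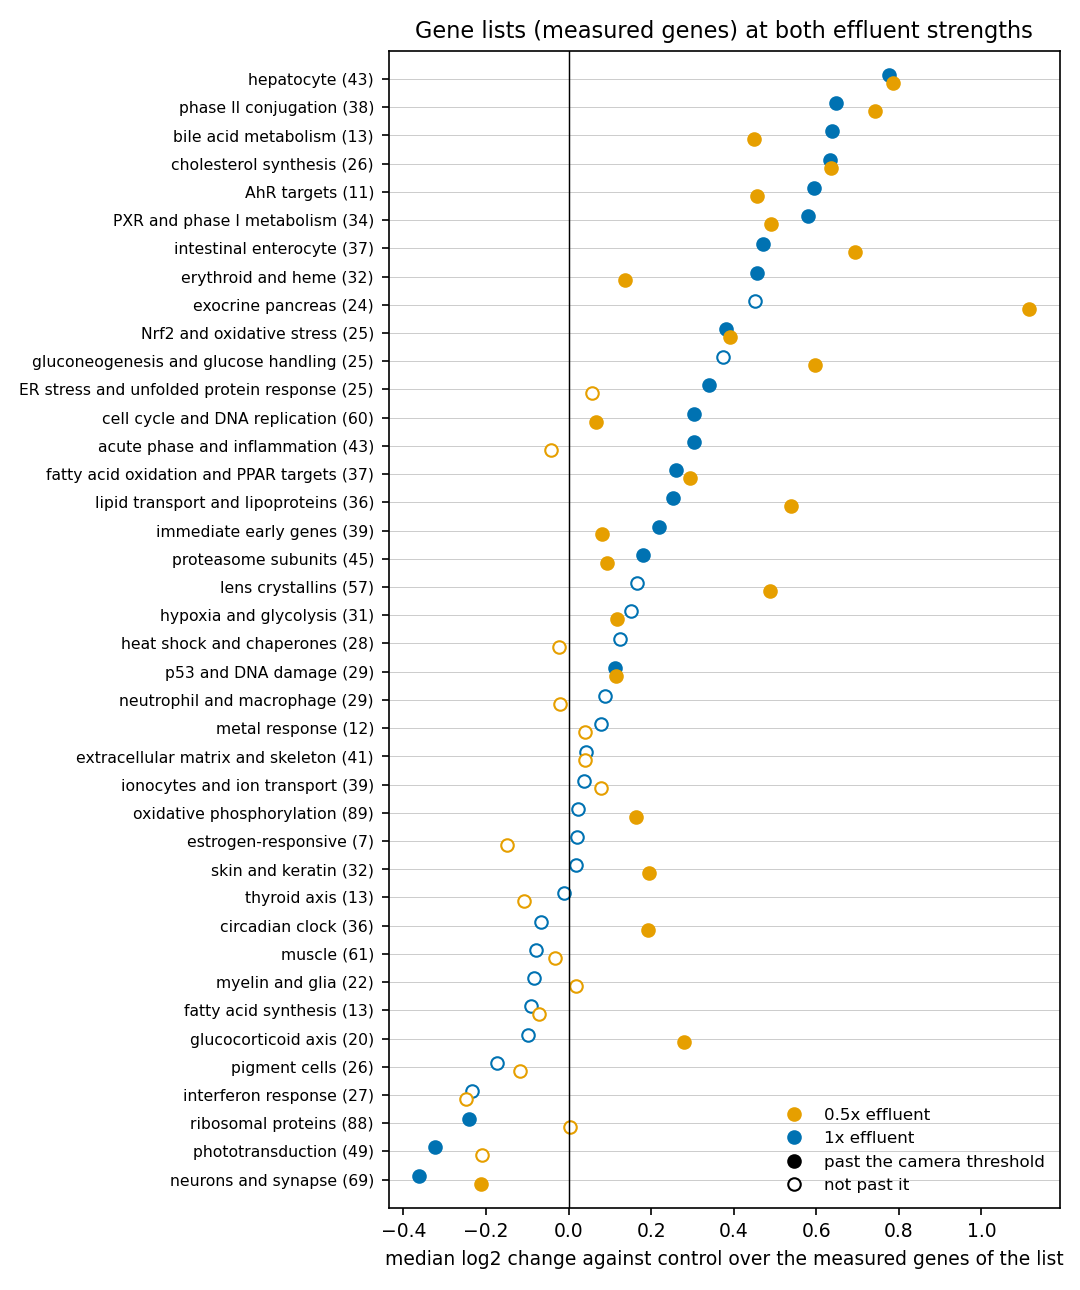
Median log2 fold change against control of the genes in each of the 40 lists at 1x (blue) and 0.5x (orange), with filled points for lists past camera's adjusted threshold at the preset correlation. Cholesterol synthesis lies at 0.63 and 0.64, hepatocyte genes at 0.78 in both and ribosomal proteins at -0.24 and 0.00.

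**Figure D4:**
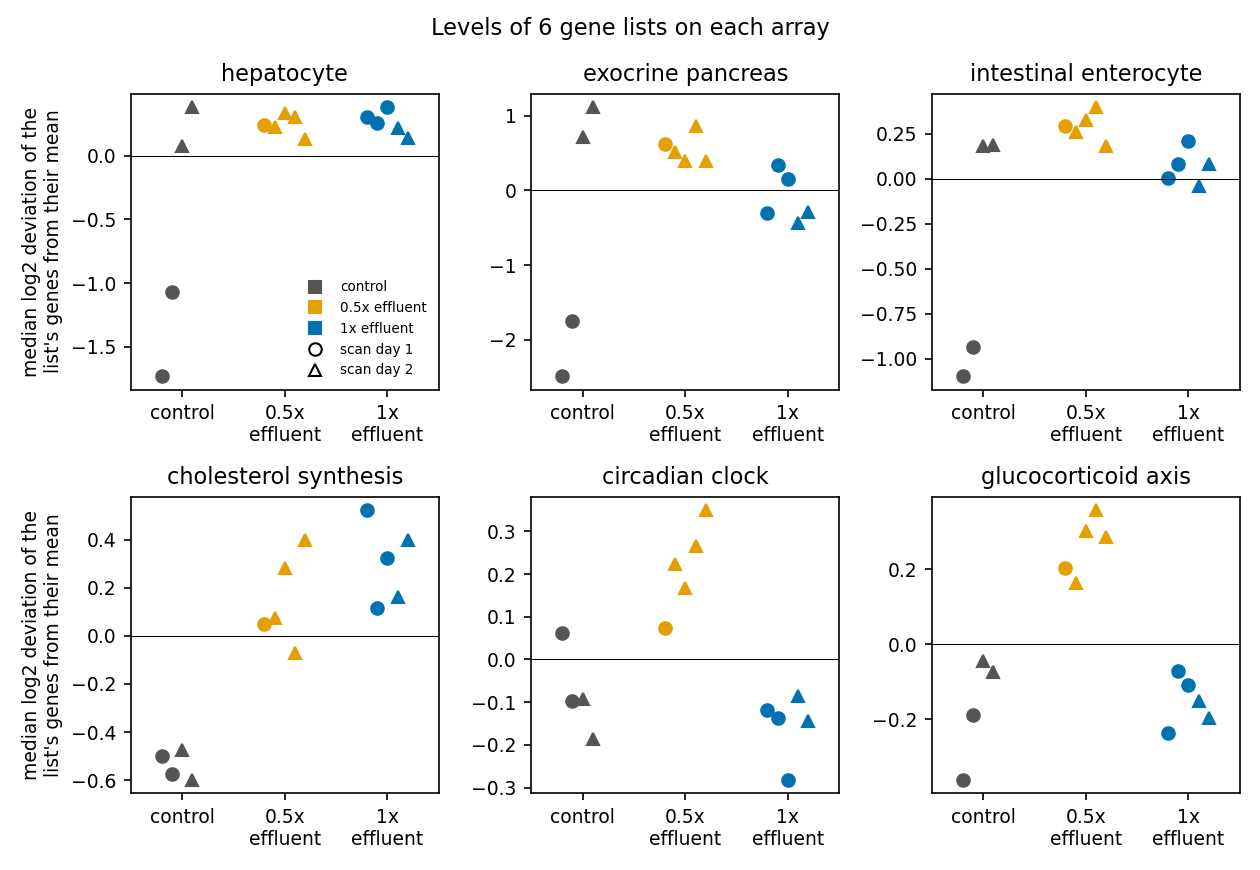
Median log2 deviation from the mean of all arrays, for each array and 6 lists, coloured by group and shaped by scan day. In hepatocyte genes control replicates 1 and 2 lie at -1.73 and -1.07 and control replicates 3 and 4 at 0.07 and 0.38, while in cholesterol synthesis all 4 lie between -0.60 and -0.47.

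The third comparison asked where larvae at 1x and 0.5x differed (n = 5 each). Brain aromatase and the vitellogenin gene vtg7 were higher at 1x, and the lists of the glucocorticoid axis, the clock and phototransduction were lower, of which only the first passed with an estimated correlation. The rise of cyp19a1b was 4.31-fold (log2 2.11 ± 0.21, adjusted p = 0.000126), and vtg7 rose 3.55-fold (1.83 ± 0.33, adjusted p = 0.00673). The largest falls were in the muscle ubiquitin ligase fbxo32 (-1.92 ± 0.32, adjusted p = 0.0041), the vitamin B6 enzyme pnpo (-1.71 ± 0.18, adjusted p = 0.000182), prrg1 (-1.67 ± 0.25, adjusted p = 0.0021), arrdc3b (-1.64 ± 0.13, adjusted p = 1.87e-05) and the lipid phosphatase lpin1a (-1.47 ± 0.14, adjusted p = 8.85e-05). Of 38803 probes, 1583 passed, 674 higher and 909 lower at 1x (42.6% higher). With normexp the split was 446 and 1017 (30.5% higher). Among genes, 185 rose and 313 fell, 25 and 41 of them by at least 2-fold, and arrays did not overlap for 8.28% of probes, where chance gives 0.794%. The count ran from 705 without 0.5x replicate 4 to 4631 without 0.5x replicate 1, and moved by more than 1.5 times also without 1x replicate 1, 2, 3 or 4 or 0.5x replicate 2, 3 or 5. With slide as a block it was 728 (285 higher, 443 lower). Within scan day 2 it was 1033 (day 1 held 1 array at 0.5x). With the authors' matrix limma called 0 (4063 at an unadjusted p under 0.05), losing every gene call here. Centred by slide, with no 1x array on slide 4, that matrix cannot test them (804 with slide as a block).

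The other large rises were in the sulfotransferase sult5a1 (1.96 ± 0.32, adjusted p = 0.00347), pfkfb2a, which controls glycolysis (1.54 ± 0.25, adjusted p = 0.00396), and the interferon-induced gbp4. That gene was at least 1.35-fold higher (adjusted p = 0.0219), well above background in 5 of 5 1x and 0 of 5 0.5x arrays, and stood at -0.07 with normexp. With slide as a block gbp4 had 1.29 (adjusted p = 0.0654) and vtg7 1.46 (adjusted p = 0.0656; 0.000285 to 0.551 over all alternatives), whereas cyp19a1b kept its call (2.00, adjusted p = 0.00422). The call of gbp4 was lost without 1x replicate 2 or 3 or 0.5x replicate 2, 3, 4 or 5 (adjusted p 0.0542 to 0.0669; 0.000112 to 0.864 over all alternatives). Estrogen-responsive genes were higher at 1x (7 genes, 2 over all probes and 3 adjusted over the list alone, median 0.24, 0.51 and -0.07 within the days, adjusted p = 0.00173; adjusted p = 0.22 with an estimated correlation). Values of vtg2 (0.07, adjusted p = 0.83), vtg5 (0.13, adjusted p = 0.769) and esr1 (0.24, adjusted p = 0.378) did not pass. Within scan days 1 and 2 the difference was 1.69 and 2.56 for cyp19a1b and 1.83 and 1.45 for vtg7.

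The glucocorticoid axis was lower at 1x than at 0.5x (20 genes, 5 over all probes and 12 adjusted over the list alone, median -0.43, -0.23 and -0.48 within the days, adjusted p = 5.46e-05). It was the only list of the 3 comparisons past the threshold with an estimated correlation (adjusted p = 0.0171). The difference was -1.26 ± 0.13 for klf9 (adjusted p = 0.000225), -0.72 ± 0.13 for tsc22d3 (adjusted p = 0.00588) and -0.66 ± 0.11 for the kinase sgk1 (adjusted p = 0.0049; 2 of 3 probes down). For fkbp5 it was -0.79 (adjusted p = 0.124), and -1.11 with slide as a block (adjusted p = 0.0385; 0.00948 to 0.56 over all alternatives). The circadian clock was lower (36 genes, 2 up and 12 down, 4 and 17 adjusted over the list alone, median -0.36, -0.35 and -0.37 within the days, adjusted p = 2.9e-07; adjusted p = 0.22 with an estimated correlation). The repressors nfil3-6 (-1.45 ± 0.14, adjusted p = 0.000114), nr1d1 (-1.19 ± 0.14, adjusted p = 0.000444) and bhlhe41 (-1.16 ± 0.13, adjusted p = 0.000337) were lower, and per1a stood at -0.77 (adjusted p = 0.0581; 0.0095 without 0.5x replicate 1). Phototransduction was lower (49 genes, 10 over all probes, 1 up and 16 down adjusted over the list alone, median -0.11, 0.04 and -0.11 within the days, adjusted p = 0.00331; adjusted p = 0.701 with an estimated correlation), with pde6ga at -1.31 ± 0.15 (adjusted p = 0.000418) and guca1aa at -1.12 ± 0.17 (adjusted p = 0.00271). Immediate early genes were higher (39 genes, 8 up and 1 down, 10 and 4 adjusted over the list alone, median 0.06, 0.05 and -0.01 within the days, adjusted p = 0.0363; adjusted p = 0.701 with an estimated correlation), with fosab at 1.28 ± 0.19 (adjusted p = 0.00168) and npas4a at 1.22 ± 0.11 (adjusted p = 6.75e-05). Acute phase genes were higher (43 genes, 4 by both adjustments, adjusted over the list alone included, median 0.16, 0.31 and -0.04 within the days, adjusted p = 0.00447; adjusted p = 0.701 with an estimated correlation). Metallothionein mt2 was lower (-0.97 ± 0.13, adjusted p = 0.0011), and with cyp19a1b it made 2 of the 24 measured sentinel genes past the threshold. The calls of immediate early and acute phase lists were lost without single arrays: the former without 1x replicate 2, 4 or 5 or 0.5x replicate 1 or 3 (adjusted p 0.0517 to 0.106; 0.00195 to 0.701 over all alternatives), the latter without 1x replicate 3 (0.0503; 7e-05 to 0.701).

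Ribosomal proteins were lower at 1x (88 genes, median -0.24, 0.02 and -0.23 within the days, adjusted p = 1.88e-10; adjusted p = 0.701 with an estimated correlation). Limma called 0 of them, also adjusted over the list alone, with 33 at an unadjusted p under 0.05; rps12 stood at -0.28 (adjusted p = 0.136). Cell cycle genes were higher (60 genes, 1 over all probes and 12 adjusted over the list alone, median 0.24, 0.19 and 0.26 within the days, adjusted p = 2.2e-09; adjusted p = 0.663 with an estimated correlation). Proteasome subunits were higher (45 genes, 1 over all probes, 9 at an unadjusted p under 0.05 and 0 by limma adjusted over the list alone, median 0.07, 0.11 and 0.20 within the days, adjusted p = 0.0025; adjusted p = 0.701 with an estimated correlation). Neuron genes (69 genes, 1 up and 2 down by both adjustments, adjusted over the list alone included, median -0.20, -0.04 and -0.13 within the days, adjusted p = 0.00447; adjusted p = 0.701 with an estimated correlation) and lens crystallins (57 genes, 1 by both adjustments, median -0.29, -0.13 and -0.26 within the days and 0.03 with slide as a block, adjusted p = 0.000854; adjusted p = 0.701 with an estimated correlation) were lower. Skin was lower (32 genes, 3 over all probes and 8 adjusted over the list alone, median -0.18, -0.17 within each day, adjusted p = 0.0312; adjusted p = 0.777 with an estimated correlation), but not without 0.5x replicate 1 (adjusted p = 0.0791; 0.00843 to 0.777 over all alternatives) or with slide as a block (-0.02, adjusted p = 0.66). Lens crystallins did not pass with it either (adjusted p = 0.728).

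The remaining 6 calls were each lost without any 1 of several arrays. Gluconeogenesis was lower (median -0.25, -0.15 and -0.26 within the days, adjusted p = 0.0363; 0.701 with an estimated correlation), but not without 1x replicate 4 or 5 or 0.5x replicate 1 (adjusted p 0.0517 to 0.127; 0.000411 to 0.701 over all alternatives). Enterocyte genes were lower (median -0.22, -0.24 and -0.25 within the days and 0.05 with slide as a block, adjusted p = 0.0438; 0.871 with an estimated correlation), but not without 1x replicate 1, 4 or 5 or 0.5x replicate 1 or 4 (0.0512 to 0.199; 2.97e-06 to 0.943). Limma called 0 enterocyte genes, with 5 at an unadjusted p under 0.05. Oxidative phosphorylation was lower (median -0.11, 0.10 and -0.03 within the days and 0.09 with slide as a block, adjusted p = 0.0482; 0.903 with an estimated correlation), but not without control replicate 1 or 3, 1x replicate 1, 2 or 3 or 0.5x replicate 3, 4 or 5 (0.0575 to 0.327; 0.000374 to 0.903). Cholesterol synthesis was higher (median 0.16, 0.25 and 0.13 within the days, adjusted p = 0.0294; 0.701 with an estimated correlation), but not without 1x replicate 1 or 5 or 0.5x replicate 1 or 4 (0.0715 to 0.0992; 0.0032 to 0.701). Heat shock was higher (median 0.19, 0.16 and 0.15 within the days, adjusted p = 0.0438; 0.672 with an estimated correlation), but not without 1x replicate 1, 3 or 5 or 0.5x replicate 1 or 4 (0.0512 to 0.127; 0.00465 to 0.672). ER stress was higher (median 0.14, 0.14 and 0.11 within the days, adjusted p = 0.0438; 0.701 with an estimated correlation), but not without control replicate 1 or 4, 1x replicate 3 or 0.5x replicate 1, 2, 3 or 4 (0.0501 to 0.133; 0.00933 to 0.701). Gluconeogenesis (-0.03, adjusted p = 0.255), enterocyte genes (0.857) and ER stress (0.15, adjusted p = 0.121) did not pass with slide as a block, and oxidative phosphorylation passed as higher at 1x (0.00218). In these lists serpinh1b (1.09 ± 0.14, adjusted p = 0.000712) was higher at 1x, and hsf2 (-0.83 ± 0.14, adjusted p = 0.00364) and trib3 (-0.71 ± 0.10, adjusted p = 0.00116) were lower. In all, 18 lists passed, 8 up and 10 down, and 6 with fry. With slide as a block 13 were up and 8 down, with the authors' matrix 16 and 7.

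The lists of chemical metabolism did not pass between the concentrations in the planned fit, but most did in some alternatives. The medians and adjusted p were 0.14 (0.194) for AhR targets, 0.03 (0.36) for PXR and phase I, 0.10 (0.284) for phase II and 0.00 (0.766) for bile acid metabolism. The differences were 0.47 for cyp1a (adjusted p = 0.415) and 0.15 for cyp3a65 (adjusted p = 0.853). Hepatocyte genes (-0.01) and Nrf2 (-0.06) had an adjusted p of 0.855 and 0.956. Higher at 1x with slide as a block were PXR and phase I (0.31, adjusted p = 0.0218; 0.019 to 0.973 over all alternatives), phase II (0.23, adjusted p = 0.00237; 0.00201 to 0.973), Nrf2 (0.17, adjusted p = 0.0441; 0.0265 to 0.997) and hepatocyte genes (0.42, adjusted p = 0.00124; 0.000989 to 0.987). Of these lists, PXR and phase I (0.21, adjusted p = 0.0265), phase II (0.19, 0.00637), Nrf2 (0.12, 0.0265) and hepatocyte genes (0.21, 0.0175) also passed with the authors' matrix, as did AhR targets (0.21, 0.0243). Extracellular matrix (0.13, adjusted p = 0.0158), fatty acid synthesis (-0.15, 0.0327), myelin and glia (-0.13, 0.015) and hypoxia and glycolysis (-0.15, 0.0158) also passed with slide as a block, against 0.616, 0.0651, 0.104 and 0.191 without. Exocrine pancreas had a median of -0.59 (adjusted p = 0.0609) and passed without control replicate 1, 2, 3 or 4, 1x replicate 2 or 3 or 0.5x replicate 3 or 5 (adjusted p 0.0156 to 0.0486).

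The comparisons against control shared their 4 control arrays. Over 38803 probes their log2 fold changes correlated at 0.728, where 20 simulations of unchanged groups against shared controls averaged 0.555. The covariance was 0.148, against 0.0230 in the simulations, a difference of 0.125 (jackknife SE of the covariance 0.0965). With the controls split in pairs between the comparisons (6 ways) the correlation ran from 0.0932 to 0.692 (0.0932 to 0.335 split by scan day). The covariance ran from 0.0288 to 0.145. Both comparisons called 895 probes up and 1620 down, counts the shared controls raise, and 22 in opposite directions. Of 0.5x calls, 69.8% were also made at 1x. Probes are not independent replicates.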

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

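Of the tests below, those of hepatocyte share, of slides in clock genes and both on cyp19a1b and vtg7 were chosen after the result was seen.

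Single arrays stood far from the rest of their group in 28 of 504 combinations of a gene or list with a group (5.56%, where chance gives about 5%), 8 of them in 0.5x replicate 1 and 5 in 1x replicate 5. Values are log2 differences from the median of the group's other arrays. In 0.5x replicate 1 they were -0.848 in ache, -0.900 in stxbp1b, -0.447 in esr1, -0.529 in g6pc1a.2, 1.01 in pck1, 1.08 in pimr132, 1.90 in gbp4 and -0.239 in the list of neurons. In 1x replicate 5 they were -1.19 in fkbp5, -0.276 in gstp1.1, 2.01 in tfr2, 0.116 in psmb7 and 0.270 in the list of ribosomal proteins. Control replicate 4 differed by -1.09 in acod1, -0.346 in guca1aa, 0.334 in pde6ga and 0.347 in trib3, and control replicate 2 by -0.259 in nr4a1 and 0.172 in the list of ER stress. Control replicate 1 differed by -0.276 in fosab. The other 1x arrays differed by -0.222 in trib3 and 0.0777 in the list of bile acid metabolism (replicate 1), 2.17 in opn1mw4 (replicate 2), and 1.73 in ccl34a.4 and -1.07 in zbtb12.1 (replicate 3). The other 0.5x arrays differed by -1.36 in fbxo32 (replicate 3), -0.351 in serpinh1b (replicate 4) and 0.212 in manf (replicate 5).

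Liver, gut and pancreas genes were lower in control replicates 1 and 2 than in control replicates 3 and 4, by -1.71 (SE 0.295) over 104 genes. A shift of slide or scan day common to all arrays is excluded, since 1x arrays of day 1 lay 0.197 (SE 0.110) above those of day 2 and 0.5x arrays 0.06 (SE 0.105). The test of a smaller hepatocyte share cannot decide, since its exocrine pancreas (-3.04, SE 0.417) and enterocyte genes (-1.20, SE 0.0801) were part of the pattern as defined. Slower development of these wells was not tested. Position 1 on the slide was shared by control replicates 3 and 4, so it cannot set control replicates 1 and 2 apart from them. The rises of these lists against control may therefore rest on these 2 wells.

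Clock and glucocorticoid genes were higher at 0.5x than at 1x. The median of 6 genes of the clock's opposite limb was higher at 1x by 0.438 (SE 0.118 over genes, not wells). Limma called only 1 (bmal1b, not with slide as a block), and clocka (-0.06) and clockb (0.02) barely differed. Wells collected at different times of the day remain a candidate. A difference between slides is excluded as the whole cause: over all 55 measured members the median per array differed by -0.368 (SE 0.0554) with slide as a block and -0.386 (SE 0.0454) without. With the block the list medians were -0.42 (clock) and -0.29 (glucocorticoid) instead of -0.36 and -0.43. The biological alternative, a difference in effluent strength, stays open and untested.

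Both cyp19a1b and vtg7 were highest at 1x. A single outlying well is excluded, since the lowest 1x array lay above the highest of the others by 0.275 in vtg7 and 0.91 in cyp19a1b. A difference between slides is excluded as the whole cause: with slide as a block the difference to 0.5x was 2.00 (SE 0.262) instead of 2.11 (SE 0.21) for cyp19a1b and 1.46 (SE 0.358) instead of 1.83 (SE 0.328) for vtg7. That ended the call of vtg7 (adjusted p = 0.0656; 0.000285 to 0.551 over all alternatives). A biological action of the effluent at 1x stays open and was not tested. Values of vtg2, vtg5 and esr1 did not pass.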

How the results depend on the processing

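Of 33 alternatives, 5 were chosen after the data were seen: without control replicates 1 and 2, scan day 1 only, scan day 2 only, scan day as a block, and the authors' matrix with slide as a block. Unless the cause is given, the cause was not tested.

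With each array left out in turn, limma's count of probes ran from 5963 to 13012 (1x against control), 1114 to 9667 (0.5x against control) and 705 to 4631 (1x against 0.5x), and that of lists from 18 to 25, 22 to 25 and 11 to 19 (lowest without 0.5x replicate 1). Of the lists called, 18 of 20, 20 of 24 and 9 of 18 kept their call in each such run, as did 69 of 74, 37 of 47 and 27 of 28 named genes. The covariance ran from 0.101 to 0.214 (jackknife SE 0.0965). The cell cycle list at 0.5x ran from -0.025 (without control replicate 4) to 0.15.

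No filter left 120 of 120 list results and 183 of 186 named gene results the same, trend and robust settings 120 and 184, and median scaling 116 and 185. Replicate numbers did not pair the arrays: over 13 pairs the correlation of their residuals ran from -0.224 to 0.493. With replicate number as a block the counts were 12834, 3984 and 1813 probes and 21, 24 and 16 lists, and 117 list results and 181 gene results stayed the same.

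Normexp gave 2035 probes at 0.5x and turned gdf9 (-0.12) and vtg2 (-0.35) at 1x and gbp4 (-0.071) between the concentrations. Quantile normalization turned ribosomal proteins at 1x (0.012) and oxidative phosphorylation between the concentrations (0.0017). Fits of only the groups compared, with fewer arrays, called 1118 probes at 0.5x and 3247 between the concentrations, and array weights (0.301 for control replicate 4 to 2.73 for 0.5x replicate 4) 10521 and 14514. A minimum change of 1.5-fold left 6287, 2317 and 1053 probes, since it asks for more, and 1 probe per named gene 3336, 1191 and 653, since fewer were tested. With an estimated correlation camera called 0, 0 and 1 lists, with 4, 8 and 4 at an unadjusted p under 0.05.

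Between the concentrations limma called 0 probes with the authors' matrix (4063 at an unadjusted p under 0.05), 728 with slide as a block and 804 with both. In the same order the values were 0.12, 0.17 and 0.17 for Nrf2, 0.21, 0.42 and 0.42 for hepatocyte, 0.038, 0.052 and 0.052 for enterocyte and 0.069, 0.089 and 0.088 for oxidative phosphorylation. The matrix turned gluconeogenesis too (0.020), and the other settings lens crystallins (0.034 and 0.026). Scan day as a block turned oxidative phosphorylation (0.018).

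Without control replicates 1 and 2 the counts were 4278, 606 and 3243 probes, with 14 lists at 0.5x. At 1x lens crystallins (-0.38), lipid transport (-0.12), exocrine pancreas (-1.02), enterocyte (-0.096), neutrophil (-0.15), skin (-0.26) and oxidative phosphorylation (-0.15) turned, and at 0.5x lens crystallins (-0.099), exocrine pancreas (-0.38), skin (-0.043) and oxidative phosphorylation (-0.028). Of the results, 83 of 120 for lists and 157 of 186 for genes stayed the same.

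Within scan day 1 the counts were 18073, 11720 and 0 probes (3204 at an unadjusted p under 0.05 for the last), and the covariance was 0.478 (0.0801 within scan day 2). At 0.5x acute phase (0.36), neutrophil (0.51) and cell cycle (-0.073) turned, and between the concentrations phototransduction (0.042), ribosomal proteins (0.017) and oxidative phosphorylation (0.098). Within scan day 2 the counts were 1556, 834 and 1033 probes. There lens crystallins (-0.30), lipid transport (-0.040), exocrine pancreas (-1.28), hepatocyte (-0.014), enterocyte (-0.18), acute phase (-0.11), neutrophil (-0.29) and hmox1a (-0.12) turned at 1x. At 0.5x lens crystallins (-0.036), exocrine pancreas (-0.39), hepatocyte (-0.011) and neurons (0.037) turned, and between the concentrations estrogen-responsive genes (-0.066), acute phase (-0.044) and immediate early genes (-0.0054). Each day held fewer arrays, with 1 at 0.5x on day 1.

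Signal over background limits ggact.2, opn1mw4, pimr132, gdf9, ggact.3 and gbp4, whose changes are given as lower bounds.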

Other observations

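Of the results below, the counts over other divisions of the arrays were planned, and no other test was run.

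Several genes of ion transport, cartilage and pigment changed although their lists did not pass against control. In ionocytes, the skin cells that move ions and ammonia, the sodium pump subunit atp1a1a.3 rose at 1x (log2 fold change 0.77 ± 0.13 SE, limma's adjusted p = 0.00173) and the ammonia channel rhcgl1 rose at 0.5x (1.36 ± 0.13, adjusted p = 9.6e-05). The calcium hormone pth1a was higher at 1x than at 0.5x (1.45 ± 0.23, adjusted p = 0.00327) and rhcgl1 was lower (-0.79 ± 0.12, adjusted p = 0.0031). The cartilage factor sox9b fell at 0.5x (-0.85 ± 0.10, adjusted p = 0.000413), while at 1x the matrix protein gene mgp fell (-0.69 ± 0.12, adjusted p = 0.00223). The pterin synthesis gene gch2 rose at 1x (1.1 ± 0.19, adjusted p = 0.00194) and impdh1b, which serves purine synthesis, fell (-0.63 ± 0.11, adjusted p = 0.00298). These calls held with each array left out in turn and with slide as a block.

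Single genes of energy use, muscle and glia passed as well, among the calls over all genes given above. Against control, pfkfb4b had a higher value at 0.5x, and it was lower at 1x than at 0.5x (-0.86 ± 0.09, adjusted p = 0.000174). The BH3 gene bnip3 fell at 1x (-0.99 ± 0.12, adjusted p = 0.000388) and at 0.5x (-0.75 ± 0.12, adjusted p = 0.00304). The fast myosin myhz1.2 fell at 1x (-0.90 ± 0.17, adjusted p = 0.00347). The glutamate transporter of glia slc1a2a fell at 1x (-0.66 ± 0.15, adjusted p = 0.00881) and was lower than at 0.5x (-0.68 ± 0.14, adjusted p = 0.0183). Except between the concentrations, whose calls the authors' matrix lost without a block, these calls held with each array left out in turn and with slide as a block.

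The counts were repeated over 100 of the 126 possible divisions of the arrays into groups of the real sizes. No other division reached the real count of probes at 1x against control (11167, highest other 7878) or at 0.5x against control (3604). The highest other there, 3575, was close: it set control replicate 4 with 0.5x replicates 2 to 5 against the rest, a division by scan day but for control replicate 3 (real count with scan day as a block 5074). At 1x against 0.5x 2 divisions were as large as the real count of 1583, the real one included. The highest other there was 8845, several times the real count. That division set 1x replicates 1 to 4 with 0.5x replicate 1 against the rest, a division by scan day but for 1x replicate 4, which points to a structure of the samples whose source was not tested. Within scan day 2 the real count between the concentrations was 1033, and with scan day as a block 1623. For the counts of lists, chance was not excluded at 1x against control (20, highest other 28, 41 divisions as large). Nor was it at 0.5x against control (24, highest other 26, 10 as large) or at 1x against 0.5x (18, highest other 20, 3 as large). Division by scan day alone, between 1x and control arrays, gave 1462 probes.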
